A study of Mus musculus with 3 samples.

How the data were processed

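The material was organoids grown from the submandibular salivary gland of C57BL/6 mice, taken from 4 animals and cultured in Matrigel with Wnt3a and R-spondin1 conditioned media, EGF, FGF2 and dexamethasone, per the labels' protocols. The labels list 3 samples. Organoids were left unirradiated (control) or received 7 Gy of photons or 7 Gy of protons in the plateau of the beam on day 5, and all were collected on day 11, with all conditions handled on the same day. They were dissociated with trypsin, stained with propidium iodide, which enters dead cells, and 45000 propidium iodide negative cells per sample were sorted and loaded on a 10x Genomics Chromium chip for 3' single-cell RNA sequencing. Each group is therefore 1 library, and the labels do not tie cells to animals.

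The authors deposited, for each library, a matrix of unnormalised counts of unique molecular identifiers (UMIs) per gene and cell barcode, with its gene and barcode lists. Per the submitters' processing notes the reads were processed with Cell Ranger 7.0.1 against mm10, while the file headers of the matrices name version 7.0.0. The annotation release and whether reads in introns were counted are not given in the sources used here. The 3 gene lists were identical, with 32285 genes. All deposited barcodes held at least 500 UMIs, which shows a filter made before deposit whose rule is not given in the sources used here. The deposited counts held 14266 barcodes and 40166701 UMIs for control, 15926 and 47514102 for photon, and 14525 and 37116107 for proton. Gene positions were taken from GENCODE mouse release 21 (GRCm38, the assembly that mm10 names) by Ensembl gene ID, and 32235 of the 32285 deposited IDs matched.

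Cells with at least 500 detected genes and at most 20% of UMIs from mitochondrial (mt-) genes were kept, which left 13219 control, 15041 photon and 13956 proton cells. Scrublet, run per library as part of scanpy 1.11.5 with an expected rate of 0.1 and a simulated ratio of 2, marked 1 control cell, 1196 photon cells and 2349 proton cells as doublets. It had marked under 0.5% of the control cells, so by the rule set beforehand it was taken not to have worked and no doublets were removed from any library. The kept counts were summed over the cells of each library and divided by the library's total, scaled to CPM. Kept totals were 39514768 UMIs for control, 46936995 for photon and 36692939 for proton.

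With 1 library per group no difference between groups can be tested, so no p-value is given. Cells are not replicates. Each ratio of CPM carries an exact 95% Poisson interval (conditional binomial, Clopper-Pearson) and each share of cells an exact 95% binomial (Clopper-Pearson) interval. Both cover counting error only, and neither covers the spread between cultures, animals or library preparations. A count of 0 was set to a floor of 3 counts in its library, which is 0.0759 CPM in control, 0.0639 in photon and 0.0818 in proton. Genes were counted as higher or lower by size alone, with a fold of at least 1.5 and a mean CPM of at least 25 over the compared libraries. For each of 25 gene lists and 15 lists of cell type markers, the median log2 CPM ratio was taken over members with a mean CPM of at least 5, with a 95% bootstrap interval over members from 2000 draws. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and tests nothing about the conditions. Of the 539 symbols in the gene lists, 4 (Mx1, Mx2, Ddit3 and Aldoa) were not analysed here.

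All kept cells were clustered together, without correction between libraries. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries. Members of the radiation response and cell cycle lists and mt-, Rpl, Rps, sex-linked and haemoglobin genes were left out first. Response and cell cycle genes outside those lists stayed eligible. Among them were Ccl5 and Cxcl10, which led cluster 9, Ddx60 in cluster 1 and Hist1h1b in cluster 7, so the clusters are not independent of the response or the cell cycle. The 30 first principal components gave 20 exact nearest neighbours per cell, weighted by their Jaccard overlap and partitioned by leidenalg 0.10.2 at resolution 0.5. Clusters were named from the marker lists only. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, which left out 3599 control, 4150 photon and 6017 proton cells with fewer. Values with the class mixture held equal averaged the CPM of the 8 clusters with at least 100 cells in each library, with the same weights in each library. For a gene that sets a cluster apart, this step can shrink its ratio by design. Such genes include Vim, Timp1 and Fdps (cluster 2), Aox3, Orm1 and Orm3 (cluster 0) and Sorbs2 (cluster 3). For them the value does not separate a change of mixture from a change within cells.

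The genes named in the text are, for each comparison, the 12 with the highest and the 12 with the lowest ratio among genes with a mean CPM of at least 25, leaving out mt-, Rpl, Rps, sex-linked and haemoglobin genes, where the fold was at least 1.25 and the interval excluded 1. To these come up to 4 members per list with a mean CPM of at least 10 and the largest ratio against control, and Cdkn1a, Mdm2, Isg15, Mki67, Krt5, Krt14, Krt7, Krt8, Aqp5 and Acta2. Not all genes that this rule names are reported here. Genes named outside this rule are said to have been chosen after their values were seen, or are further members of a list given with it. The groups, comparisons, lists, this rule and the first set of alternatives were fixed before the data were examined.

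The counting rule was tested on simulated data, with 200 genes changed by known folds at the depth of each comparison. Among 5787 simulated genes for photon against control, 5800 for proton against control and 5645 for proton against photon, it called 100% of measured genes changed 1.75-fold, 2-fold or 4-fold, none (0%) of those changed 1.25-fold, and 0 unchanged genes in each of the comparisons. The counting intervals held the true ratio for 95.2%, 95.7% and 95.4% of genes. These simulations hold counting noise only.

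Alternatives covered the cell filter, doublets, scaling, weighting of cells, class mixture, thresholds, clustering and thinning. Further alternatives, chosen after seeing the data, left out the 10% of cells with the highest doublet scores, left out cluster 5, centred ratios within 10 classes of gene length, and left the leading genes of the named clusters out of clustering. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.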

Results

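Transcripts were counted in single cells of mouse submandibular gland organoids, which are 3-dimensional epithelial cultures grown from dissociated gland. There were 3 groups of 1 library each, unirradiated control, 7 Gy of photons and 7 Gy of protons, collected 6 days after irradiation. After filtering, the control library held 13219 cells with a median of 2757 UMIs and 1482 genes per cell. The photon library held 15041 cells with medians of 2808 UMIs and 1454 genes, and the proton library 13956 cells with medians of 2223 UMIs and 1229 genes. Mitochondrial genes held 3.29% of UMIs in control, 2.23% in photon and 1.80% in proton, and ribosomal protein genes held 16.5%, 18.6% and 20.3%. No difference below has a replicate check, and each compares libraries rather than conditions. Ranges in parentheses after a ratio or a share are 95% counting intervals, and coordinates are on GRCm38.

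The first comparison asked how organoids that had received photons differed from unirradiated ones. Interferon-stimulated genes were far higher in the photon library. Of 33 measured genes of the type I interferon response, 32 were at least 1.5-fold higher and 1 was lower, with a median log2 ratio of 3.26 (bootstrap interval over members 2.35 to 4.19). Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), which encodes a ubiquitin-like protein, stood at 49.2 CPM in control and 1267 CPM in photon, a ratio of 25.7 (24.6 to 26.9). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), an RNA-binding antiviral effector, stood at 1.27 and 385 CPM, a ratio of 304 (231 to 410).

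The largest ratios beside Ifit3 were those of the GTPase Iigp1 at 270 (154 to 522), the chemokine Ccl5 at 162 (117 to 230) and the antiviral enzyme Rsad2 at 153 (98.7 to 250). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) stood at 0.936 CPM in control and 152 CPM in photon. Zbp1, a sensor of left-handed nucleic acid, was 78.5-fold higher, and the chemokine Cxcl10 was 47.0-fold higher (37.3 to 60.2). Trim30a was 34.4-fold, Ifit1 34-fold and Apol9a 26.3-fold higher. With the class mixture held equal Iigp1, Rsad2, Ccl5 and Cxcl10 were 137-fold, 88.2-fold, 73.8-fold and 23.3-fold higher. Counts of Ifit3 and Ifit3b, H2-Q6 and H2-Q7, Apol9a and its copy, and Trim30a and its paralogs are uncertain, because their near-identical sequences can share reads.

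All 17 measured genes of MHC class I presentation were higher in photon, with a median log2 ratio of 2.25. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), the light chain of MHC class I, stood at 193 CPM in control and 1643 CPM in photon, a ratio of 8.50 (8.30 to 8.70). H2-Q7 was 44.2-fold higher, and Nlrc5, a transcriptional activator of these genes, 5.65-fold higher. Among 12 measured nucleic acid sensors 8 were higher and none (0) lower, with a median log2 ratio of 1.08. They included Ddx58, which encodes RIG-I, at 5.09-fold and Ifih1, which encodes MDA5, at 3.19-fold. Each of these lists lay at the 100th percentile of matched random lists.

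**Figure D1:**
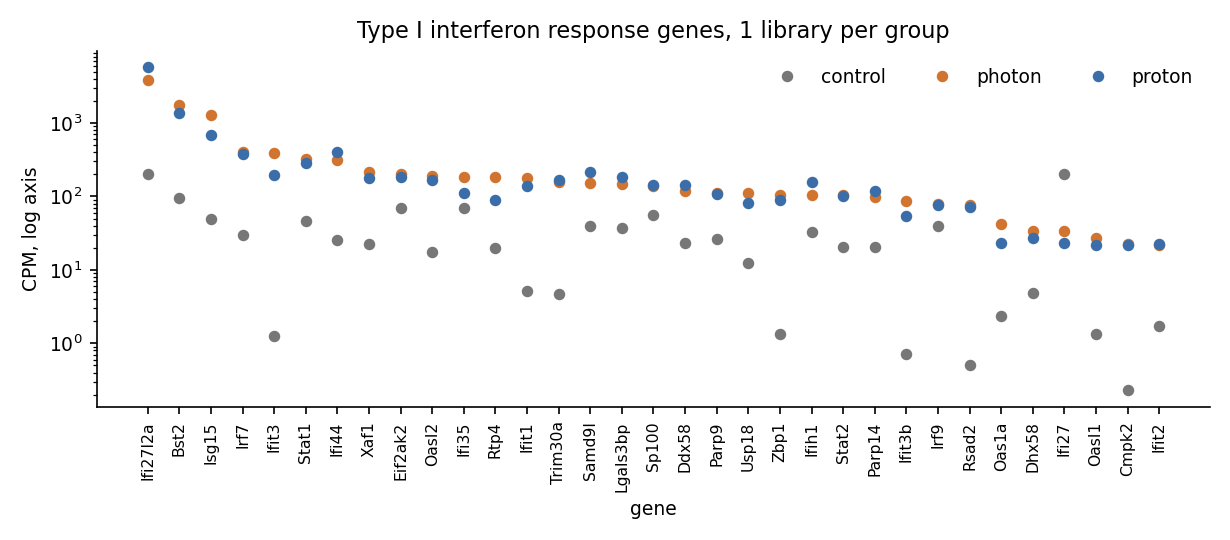
CPM (log axis) of each measured gene of the type I interferon response in the control, photon and proton libraries, 1 point per library, with genes ordered by their photon value. Both irradiated libraries lie above control for 32 of the 33 genes, and Ifi27 lies below it in both.

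Cell cycle genes were also higher in photon than in control. Of 42 measured G2 and M phase genes 36 were higher and 0 lower, with a median log2 ratio of 1.91 (2.04 times control when summed), and of 32 S phase genes 23 were higher and 0 lower, with a median of 1.08. The proliferation marker Mki67 stood at 11.0 CPM in control and 37.4 CPM in photon, a ratio of 3.41 (3.07 to 3.80). The cyclin Ccna2 was 6.70-fold, the ubiquitin-conjugating enzyme Ube2c 5.74-fold, the ribonucleotide reductase subunit Rrm2 5.10-fold and the replication helicase subunit Mcm5 4.63-fold higher. The marker list for cycling cells had a median of 2.16, with 9 of 10 genes higher. With the class mixture held equal the G2 and M phase and S phase medians were 0.47 and 0.29, and Mki67, Ccna2, Ube2c, Rrm2 and Mcm5 stood at 1.13, 2.00, 1.64, 1.95 and 1.85 times control. Cholesterol synthesis genes were higher in 10 of 18 cases and lower in 0, with a median of 0.75, and Fdps, which makes farnesyl diphosphate, was 3.52-fold higher (3.36 to 3.69). This median was 0.17 and Fdps 1.84-fold higher with the mixture held equal.

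Among 28 measured p53 targets 9 were higher and 2 lower in photon, with a median log2 ratio of 0.30. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes the cyclin-dependent kinase inhibitor p21, stood at 158 CPM in control and 316 CPM in photon, a ratio of 1.99 (1.94 to 2.05). Mdm2, the ubiquitin ligase of p53, stood at 72.1 CPM in control and 121 CPM in photon, 1.67-fold higher, with the death receptor Eda2r 1.54-fold and Zmat3 1.45-fold higher. Plk2 and Btg2, which are on the same list, stood at 0.777 and 0.832 times control, but their log2 ratios were 0.03 and 0.317 with the mixture held equal, so no direction is read from them. The ER stress list had a median of 0.33, with 6 genes higher and 3 lower of 18, and the chaperone cofactor Sdf2l1 was 2.90-fold higher while Herpud1 stood at 0.5 times control. The ER stress median was 0.09 and Sdf2l1 was 1.60-fold higher with the mixture held equal.

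Several genes were much lower in photon than in control. Ifi27 (ENSMUSG00000064215, chromosome 12, 103434211 to 103440239), the 1 member of the interferon list that was lower, stood at 201 CPM in control and 33.5 CPM in photon, a ratio of 0.166 (0.158 to 0.176). The acute phase proteins Orm3 and Orm1 stood at 0.200 and 0.273 times control, and their counts can share reads. The aldehyde oxidase Aox3 stood at 136 CPM in control and 28.2 CPM in photon, a ratio of 0.207. The water and glycerol channel Aqp3 stood at 0.280, the circadian factor Hlf at 0.294, the chemokine Cxcl3 at 0.320 and Mill1 at 0.321 times control. 9130230L23Rik, Sprr2d and Gm48099 lay between 0.368 and 0.372 times control. Orm3, Aox3, Orm1, Sprr2d and Hlf stood at 0.424, 0.430, 0.507, 0.678 and 0.683 times control with the mixture held equal. Aox3, Orm3 and Orm1 led cluster 0, which held mostly control cells.

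Oxidative stress genes were lower in 3 of 21 cases and higher in 0, with a median log2 ratio of -0.17, and the cystine transporter Slc7a11 stood at 0.409 and the glutathione transferase Gstm1 at 0.390 times control. NF-kB response genes were lower in 3 of 17 cases and higher in 0 (median -0.25), YAP targets in 5 of 14 and 0 (-0.26), and mitophagy genes in 3 of 18 and 0 (-0.19). Relative to the median of all genes these 4 medians were -0.06, -0.14, -0.15 and -0.07, at percentiles of 8.96, 11.89, 12.85 and 15.29 among matched random lists, and no direction is read from them. The nuclear-retained RNAs Malat1 and Neat1 stood at 0.613 and 0.453 times control, and at 0.79 and 0.621 times with the mixture held equal. The RNA quality list of 4 genes had a median of -0.70. Histone and chromatin factors had a median of 0.32 (3 of 19 higher, 0 lower), with Hist1h2bc, a histone gene whose copies can share reads, 6.78-fold higher. Apoptosis regulators had a median of 0.17 (4 of 22 higher, 0 lower), and the respiratory chain 0.22 (3 of 27 higher, 0 lower). With the mixture held equal the YAP, histone and respiratory chain medians were -0.05, 0.06 and 0.08.

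Other lists had medians whose sign depended on the scaling, the mixture or the members taken, and no direction is read from them. These were DNA repair at 0.11, senescence and secretory factors at -0.14, immediate early and heat shock genes at -0.05, matrix genes at 0.06, hypoxia and glycolysis at -0.00, Notch at -0.17, Wnt targets at -0.16 and EGF family ligands at 0.29. Summed over their members, the senescence, Wnt and hypoxia lists stood at 1.24, 1.20 and 1.34 times control and the matrix list at 0.963, against the sign of their medians. Single members stood apart, among them the intermediate filament gene Vim at 6.98-fold, the protease inhibitor Timp1 at 2.56-fold and the growth factor Areg at 1.77-fold higher. Vim was 2.89-fold and Timp1 1.41-fold higher with the mixture held equal, but both were among the leading genes of cluster 2. Of the sex-linked genes 2 were measured, and neither passed 1.5-fold.

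The ductal keratins Krt8 and Krt7 were 1.95-fold (1.90 to 2.00) and 1.66-fold higher in photon than in control. The luminal duct list had a median log2 ratio of 0.36, with 3 of 10 measured members higher, 0 lower and 7 within 1.5-fold. The basal keratins Krt14 and Krt5 stood at 1.37 and 1.12 times control. The basal duct list had a median of -0.15 and the squamous list 0.19, but their summed members stood at 1.07 and 0.832 times control, and the intercalated duct list, with 3 measured genes, 0.23. Krtdap, a product of differentiating keratinocytes, was 4.92-fold higher, or 2.79-fold with the mixture held equal. Few acinar and myoepithelial markers were measured. The acinar genes Amy1, which encodes an amylase, and Aqp5, a water channel, stood at 41.5, 21.4 and 33.7 CPM and at 11.9, 13.8 and 12.0 CPM in control, photon and proton, and the contractile gene Acta2 at 2.10, 4.52 and 2.89 CPM. Aqp5 and Acta2 were lower in each irradiated library than in control once the class mixture was held equal. Too few members were measured for a median in the acinar list (2 genes), the ionocyte list (1 or 2), the pericyte, endothelial and neural lists (1 each), and the fibroblast, immune, erythroid, myoepithelial and granular tubule lists (0).

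In all, 333 genes were at least 1.5-fold higher and 474 lower in photon among 5790 genes, so that 41.3% of these were higher. The share was 62.6% when scaled by the median of gene ratios, which moved the median log2 ratio of all genes from -0.11 to -0.01, and 64.1% with the mixture held equal. It was 63.5% when ratios were centred within classes of gene length, where 258 of the 333 higher genes and 158 of the 474 lower genes kept their place. Relative to the median of all genes, the interferon and p53 medians were 3.37 and 0.41.

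**Figure D2:**
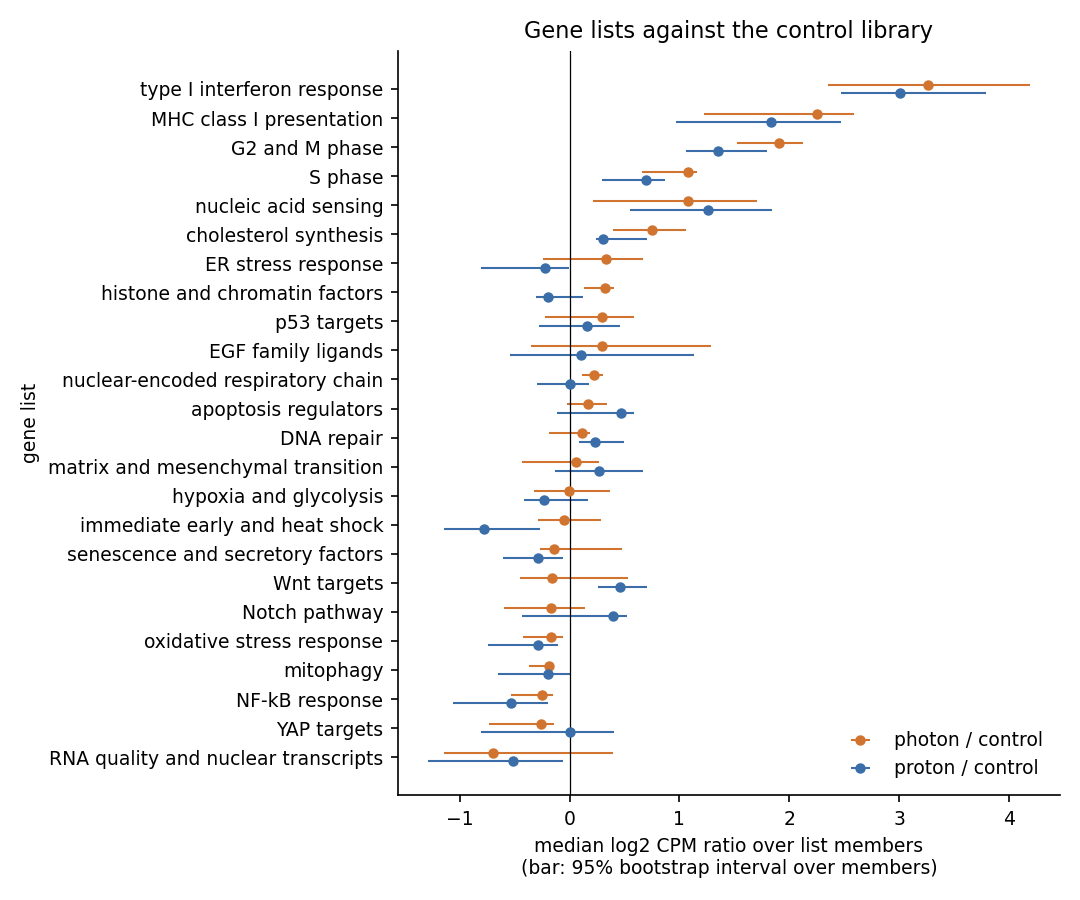
Median log2 CPM ratio over the measured members of each gene list, photon against control and proton against control, with bars for the 95% bootstrap interval over members. The interferon, MHC class I, G2 and M phase and S phase lists lie to the right in both comparisons, from 0.69 to 3.26, while the immediate early and heat shock list lies at -0.05 in photon and -0.78 in proton.

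The second comparison asked the same of protons. The interferon genes were again far higher than in control, with 32 of 33 measured genes higher, 1 lower and a median log2 ratio of 3.01 (2.47 to 3.79). Iigp1 was 250-fold higher (143 to 485), Ccl5 221-fold (160 to 314), Ifit3 157-fold (119 to 211) and Rsad2 143-fold (92.3 to 234). Ccl5 and Rsad2 were 102-fold and 91.9-fold higher with the mixture held equal, and Iigp1 moved from a log2 ratio of 7.968 to 6.662. Isg15 stood at 680 CPM, 13.8 times control (13.2 to 14.5). Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680), a small interferon-inducible protein gene, stood at 203 CPM in control, 3810 CPM in photon and 5803 CPM in proton, and was 28.6-fold higher in proton (28.0 to 29.2).

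Zbp1 was 65.8-fold, H2-Q7 35.8-fold, Trim30a 35.7-fold, Ifit1 27.2-fold, the helicase Ddx60 26.2-fold and Ifi203 17.1-fold higher in proton than in control. MHC class I genes were higher in 15 of 17 cases and lower in 0 (median 1.83), with B2m 6.34-fold higher, and nucleic acid sensors were higher in 9 of 12 and lower in 0 (1.26), with Ddx58 6.07-fold and Ifih1 4.84-fold higher. Cell cycle genes were higher too, with G2 and M phase genes higher in 31 and lower in 1 of 42 (1.35, or 1.36 times control when summed) and S phase genes higher in 17 and lower in 1 of 31 (0.69). Mki67 stood at 44.1 CPM, 4.02 times control (3.61 to 4.48), and the cycling marker list had a median of 1.61. With the mixture held equal the G2 and M phase and S phase medians were 0.475 and 0.156, and Mki67 stood at 1.58 times control.

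The p53 targets were mixed in proton, with 9 higher and 6 lower of 29 and a median log2 ratio of 0.16, which was 0.05 with the mixture held equal. Zmat3 was 2.49-fold, Eda2r 2.26-fold and Mdm2 2.04-fold (1.95 to 2.14) higher, whereas Cdkn1a stood at 186 CPM, 1.17 times control (1.13 to 1.21). This was 1.03 with the mixture held equal, and within clusters 1 to 4, 6 and 7 Cdkn1a stood at 0.611 to 1.03 times control, against 1.26 (1.04 to 1.52) in cluster 0 and 4.04 (2.13 to 7.14) in cluster 5, so no direction is read from it. Plk2 and Btg2 stood at 0.382 and 0.355 times control, with Btg2 at 0.573 when the mixture was held equal. Apoptosis regulators had a median of 0.47 (7 of 22 higher, 1 lower), with the apoptosome gene Apaf1 2.56-fold and the survival gene Bcl2 1.94-fold higher. Wnt targets had a median of 0.46 (4 of 12 higher, 1 lower), led by the adhesion receptor Cd44 at 2.23-fold, and the matrix list 0.27 (7 of 19 higher, 3 lower), with the integrin Itga3 at 2.57-fold and Vim at 4.06-fold. With the mixture held equal the Wnt and matrix medians were 0.28 and 0.06, and Vim was 2.52-fold higher.

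Immediate early and heat shock genes were lower in proton than in control in 10 of 18 cases and higher in 0, with a median log2 ratio of -0.78. Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), a subunit of the AP-1 transcription factor, stood at 931 CPM in control and 176 CPM in proton, a ratio of 0.189 (0.185 to 0.195). The phosphatase gene Dusp1 stood at 0.260, the chaperone Hspb1 at 0.346 and the stress response gene Ier3 at 0.350 times control. The list median was -0.335 with the mixture held equal. NF-kB response genes were lower in 8 of 17 cases and higher in 0 (-0.53), with the chemokines Cxcl2 and Ccl20 at 0.170 and 0.102 times control, and Ccl20 at 0.164 with the mixture held equal.

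The lowest gene in proton was Psca (ENSMUSG00000022598, chromosome 15, 74714839 to 74717069), which encodes a surface protein of epithelial cells. It stood at 83.5 CPM in control, 68.2 CPM in photon and 3.33 CPM in proton, a proton ratio of 0.0398 (0.0330 to 0.0477). Ifi27 stood at 23 CPM, 0.114 times control (0.106 to 0.123), and Aox3, Orm3 and Orm1 at 0.145, 0.149 and 0.201 times control. The cold-inducible RNA-binding protein gene Cirbp stood at 0.181, the matricellular gene Ccn1 at 0.184, the glutathione-degrading Chac1 at 0.195, the glutathione transferase Gstp1 at 0.201 and the chemokine Ppbp at 0.204 times control. Psca stood at 0.0961 with the mixture held equal, Ccn1 at 0.320, Chac1 at 0.349, Ppbp at 0.408, Aox3 at 0.514, Orm1 at 0.605 and Orm3 at 0.697 times control. Within cluster 0, which these last 3 genes led and which held 7081 control and 503 proton cells, Aox3 stood at 0.611, Orm1 at 1.05 and Orm3 at 1.18 times control. In clusters 2 to 4, 6 and 7 they stood at 0.127 to 0.412, 0.140 to 0.451 and 0.103 to 0.290 times control. These ranges leave out clusters 1 and 5, where Aox3 stood at 0.545 (0.361 to 0.86) and 0.653 (0.26 to 1.36) times control.

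Senescence and secretory factors were lower in 8 and higher in 4 of 24 cases in proton (median -0.29), oxidative stress genes lower in 7 and higher in 1 of 21 (-0.29), and mitophagy genes lower in 7 and higher in 0 of 18 (-0.20). ER stress genes were lower in 7 of 18 and higher in 0 (-0.23), with Herpud1 at 0.319 times control. The oxidative stress, mitophagy and ER stress medians lay at percentiles of 4.045, 9.13 and 7.8 among matched random lists. Malat1 stood at 0.409 and Neat1 at 0.959 times control (1.12 with the mixture held equal), and the RNA quality list had a median of -0.52 (0.428 times control when summed). Cholesterol synthesis genes were higher in 6 of 18 cases and lower in 0 (0.30, or 0.21 with the mixture held equal), with Fdps 2.11-fold higher. Medians of the other lists, from which no direction is read, were 0.23 for DNA repair, 0.00 for the respiratory chain, 0.00 for YAP targets, 0.40 for Notch, 0.11 for EGF family ligands, -0.23 for hypoxia and glycolysis and -0.20 for histone and chromatin factors. The Notch median was -0.04 with the mixture held equal, and the summed YAP targets stood at 0.850 times control. The summed histone list stood at 0.531 times control, and at 0.486 to 0.635 times in clusters 0 to 4, 6 and 7 and 0.957 times in cluster 5, with H3f3b, its most abundant member, at 0.366.

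Among basal keratins in proton, Krt15 stood at 0.317, Krt14 at 0.531 (0.524 to 0.539) and Krt5 at 0.818 times control. The basal duct list had a median of -0.33, which was -0.71 after length centring. Within clusters 0 to 7 Krt15 stood at 0.271 to 0.542 times control, Krt14 at 0.303 to 0.800 times in clusters 0 to 4 and 7 but at 1.03 and 1.14 times in clusters 5 and 6, and Krt5 at 0.647 and 0.687 times in clusters 0 and 3 but at 0.923 to 1.20 times in the other 6. The epithelial adhesion gene Epcam stood at 0.570 times control, Krt7 at 1.01 and Krt8 at 1.64, and the luminal duct list at a median of -0.04, which was 0.05 after length centring. Krtdap was 7.13-fold higher, though not in each cluster, and Slc12a2, the basolateral chloride cotransporter of secretory epithelium, 2.84-fold higher. The squamous list had a median of -0.27 (-0.098 after length centring) and the intercalated duct list, with 4 measured genes, 0.54. Of 5870 genes 633 were higher and 874 lower, and 426 and 550 of them kept their place when ratios were centred within classes of gene length.

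The third comparison set the irradiated libraries against each other, to ask how protons differed from photons at the same dose. The interferon list was close between them, with 2 genes higher and 6 lower in proton of 33 and a median log2 ratio of -0.16, while the sum of its members was 1.06 times photon. Cxcl10 stood at 85.7 CPM in photon and 27.3 CPM in proton, a ratio of 0.318 (0.296 to 0.341), Ifit3 at 0.515 and Isg15 at 0.537 (0.529 to 0.545) times photon. Ddx60 was 1.93-fold, Ifi27l2a 1.52-fold, Ifih1 1.52-fold and Ccl5 1.36-fold higher in proton. MHC class I genes had a median of -0.35, with 2 higher and 5 lower of 17, which was -0.05 after centring within classes of gene length, and nucleic acid sensors a median of 0.00.

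The ER stress, immediate early, senescence and histone lists were lower in proton than in photon. The ER stress list had 10 of 18 genes lower, 0 higher and a median log2 ratio of -0.66, with the disulfide isomerase Pdia6 at 0.284 times photon (0.274 to 0.294). The immediate early list had 12 lower and 1 higher of 19 (-0.68), with Jun at 0.255 (0.248 to 0.262), Fos at 0.270, Dusp1 at 0.289 and Ier3 at 0.309 times photon. Senescence and secretory factors had 12 lower and 0 higher of 23 (-0.61), with Cxcl2 at 0.247, and the histone list had 9 lower and 1 higher of 19 (-0.58), with the replacement histone gene H3f3b at 0.340. Centred within classes of gene length these medians were -0.33, -0.45, -0.32 and -0.35. With the mixture held equal the senescence median was -0.26 and the histone median -0.38.

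Psca again had the lowest ratio, 0.0487 (0.0403 to 0.0584), and its log2 ratio of -4.359 was -3.359 as a mean over cells. Slbp, which binds the ends of histone mRNAs, stood at 0.289, the transcriptional regulator Cited2, the tubulin regulator Stmn1 and Coq7 at 0.295, Rrs1 at 0.297, Oat at 0.299 and Utp3 at 0.300 times photon. S phase genes had a median of -0.33 (16 lower and 1 higher of 34) and G2 and M phase genes -0.43 (17 lower and 1 higher of 48), but the G2 and M phase median was 0.00 with the mixture held equal, and Mki67 was 1.18-fold higher in proton (1.10 to 1.26). Cdkn1a stood at 0.588 times photon (0.572 to 0.605), and p53 targets had a median of -0.18 (4 higher, 6 lower of 29). Cholesterol genes had a median of -0.36, which was -0.11 with the mixture held equal and -0.22 after length centring.

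The highest ratios in proton over photon belonged to Lars2, the mitochondrial leucyl-tRNA synthetase, at 4.22 (4.05 to 4.40), the noncoding RNA Gm42418 at 3.51 and AY036118 at 3.37. Gm42418 and AY036118 overlap on opposite strands of chromosome 17, so their counts are uncertain. Whether the reads counted for Lars2, Gm42418 and AY036118 came from transcripts of those genes was not tested. Gm42418 alone stood at 4148 CPM in control, 3971 in photon and 13920 in proton. They were followed by the kinase Camk1d at 2.8, Cmss1 at 2.77, the phosphodiesterase Pde3b at 2.66, Bnc2 at 2.63, Cpeb4 at 2.56, Fat2 at 2.54, Zfp827 at 2.52, Lrrc41 at 2.48 and Pum2 at 2.47. Neat1 was 2.12-fold higher in proton than in photon while Malat1 stood at 0.667 times photon, and the RNA quality list had a median of -0.27. Xist, which overlaps its antisense partner Tsix, was 1.99-fold higher in proton than in photon.

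Krt14 stood at 0.389 times photon (0.384 to 0.394), Krt15 at 0.338, Epcam at 0.482, Krt7 at 0.607 and Krt8 at 0.844. The luminal duct list had a median of -0.56, the basal duct list 0.24 (0 higher and 3 lower of 9, and 0.559 times photon when summed), the squamous list -0.27, the intercalated duct list 0.30 and the cycling list -0.43. After length centring the luminal duct and cycling medians were -0.29 and -0.27. The basal duct and squamous medians were then -0.17 and 0.04, so no direction is read from those lists. Remaining medians were -0.12 for NF-kB, -0.05 for oxidative stress (1.03 times photon when summed), -0.08 for mitophagy, -0.18 for the respiratory chain, 0.23 for apoptosis (0.942 when summed), -0.21 for EGF family ligands and -0.25 for hypoxia and glycolysis. These lists lay at percentiles from 5.4 to 72.11 among matched random lists, and the mitophagy and respiratory chain medians were 0.04 and 0.12 after length centring. No direction is read from any of them. The lists of Wnt targets at 0.47, Notch at 0.43, YAP targets at 0.30, matrix genes at 0.22 and DNA repair at 0.15 gave 0.13, 0.18, -0.14, -0.31 and -0.25 after length centring. Wnt targets lay at a percentile of 94.99 and Notch at 81.16, inside the central 95% of matched random lists. No direction is read from these lists either.

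Ratios followed gene length in each comparison. Across genes, which are not independent replicates, Spearman's rho between gene length and log2 ratio was -0.495 for photon against control, 0.373 for proton against control and 0.654 for proton against photon. The 581 longest genes, with a median length of 256 kb, had a median log2 ratio of 0.75 in proton against photon, and the 582 shortest, with 3.02 kb, -0.35. In that comparison 1318 genes were higher and 948 lower of 5814, and 212 (16.1%) and 413 (43.6%) of them kept their place after centring within length classes. The share of higher genes was 58.2%, against 40.5% after that centring and 41.9% with the mixture held equal.

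**Figure D3:**
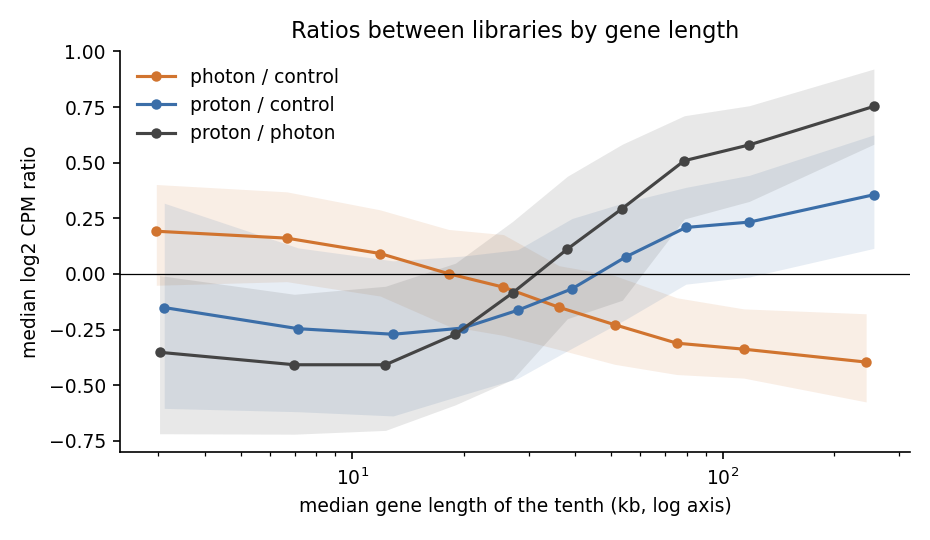
Median log2 CPM ratio in 10 classes of genes ordered by gene length (kb, log axis) for photon against control, proton against control and proton against photon, with bands from the lower to the upper quartile of genes. Longer genes lie lower in photon and higher in proton against control, and the proton to photon medians run from -0.35 in the shortest class to 0.75 in the longest.

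Clustering of all cells gave 10 clusters. Cluster 3 was named luminal duct-like, cluster 6 squamous-like (Krt13, Krt6a and Sprr1b highest there) and cluster 7 cycling-like (Top2a, Mki67 and Cdk1). The luminal duct markers summed to 18430 CPM in cluster 3, 14430 in cluster 8 and 12320 in cluster 6. Cldn3, Cldn4, Wfdc2 and Ltf were highest in cluster 3, Krt7, Krt8, Krt18 and Epcam in cluster 8, and Krt19 and Ehf in cluster 6. The intercalated duct markers Gstt1, Cftr and Slc12a2 and the granular tubule marker Klk1b26 were also highest in cluster 3. Its name therefore does not separate types of duct. Interferon genes were higher in every cluster with at least 100 cells per library, clusters 0 to 7. The list medians lay between 2.75 and 3.39 for photon and between 2.58 and 3.30 for proton. MHC class I medians lay between 1.97 and 2.42 for photon and between 1.49 and 1.92 for proton. Isg15 in the luminal duct-like cluster stood at 59.1 CPM in control, 1387 in photon and 790 in proton. It was lower in proton than in photon in each of these clusters except cluster 5, at ratios of 0.476 to 0.702, and 1.94 in cluster 5.

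Cdkn1a stood at 426, 650 and 392 CPM in control, photon and proton in the luminal duct-like cluster, the highest of clusters 0 to 7 in each library. The single genes given by cluster were chosen after their values were seen. Jun stood at 0.189 to 0.555 times photon in proton within these clusters, and Gm42418 at 2.71 to 3.77 times. Ifi27 was lower than control in each of them apart from cluster 5, at 0.107 to 0.203 times in photon and 0.0552 to 0.193 times in proton. In cluster 5 it stood at 0.404 times control in photon, and its proton value of 1 UMI is not read (0.0045 to 1.01). Immediate early medians for proton against control lay between -1.15 and 0.02, with only cluster 5 above 0. The p53 medians lay between -0.02 and 0.61 for photon and between -0.17 and 0.61 for proton. In the cycling-like cluster the summed G2 and M phase genes stood at 0.677 times control in photon (0.659 to 0.695) and 0.544 times in proton (0.528 to 0.561), with medians of -0.62 and -0.76. In clusters 0 to 6 the sums stood at 1.15 to 2.24 times control in photon. In proton they stood at 1.06 to 1.86 times in clusters 1, 2, 4 and 6 and at 0.830 to 0.872 times in clusters 0, 3 and 5, where medians of few counts lay above 0.

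The luminal duct-like cluster held 6.71% of control, 20.5% of photon and 16.4% of proton cells, the squamous-like cluster 8.85%, 5.85% and 3.35%, and the cycling-like cluster 0.756%, 5.74% and 3.57%. No direction is read from these shares, because genes that define the clusters differed between libraries. Psca, for example, led the squamous-like cluster, at 620, 928 and 37.8 CPM there, and with the 50 leading genes of both clusters left out the luminal duct-like shares were 17.2%, 26.1% and 14.8%. Clusters 0, 1 and 5 held 70.2%, 82.1% and 78.5% of their cells from 1 library (control, proton and control) and need not be cell types, and cluster 5 was shallow, with a median of 927 UMIs and 8.97% mitochondrial UMIs.

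**Figure D4:**
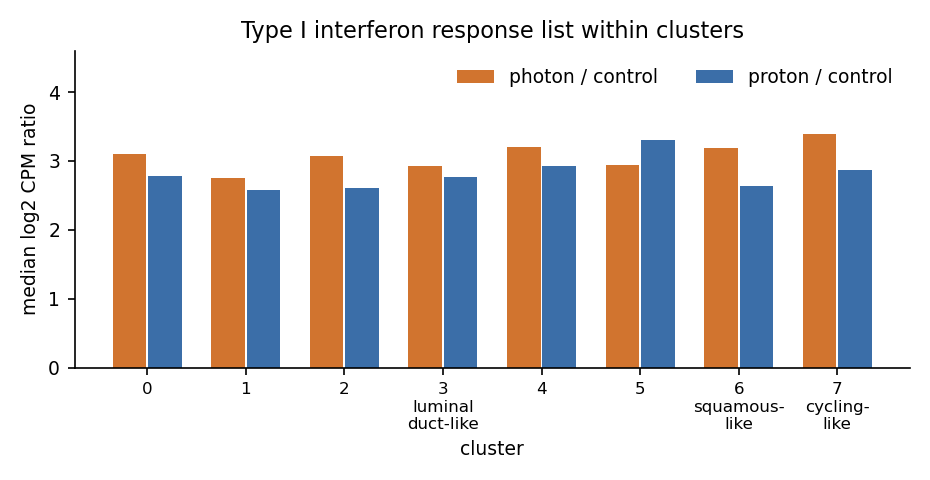
Median log2 CPM ratio of the type I interferon response list within clusters 0 to 7, photon against control and proton against control. Bars lie between 2.58 and 3.39 in every cluster shown, including the luminal duct-like, squamous-like and cycling-like ones.

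In shares of cells, with each cell thinned to 2000 UMIs, Isg15 was detected in 7.55% of control cells (7.03 to 8.09), 81.1% of photon cells (80.3 to 81.8) and 64.1% of proton cells (63.1 to 65.2). Cdkn1a was detected in 21.3% (20.5 to 22.2), 36.2% (35.3 to 37.1) and 26.6% (25.6 to 27.6). Top2a, a topoisomerase of dividing cells, was detected in 1.39% of control cells (1.17 to 1.65), 7.00% of photon cells (6.52 to 7.49) and 7.31% of proton cells (6.74 to 7.90), and Mki67 in 1.10%, 5.40% and 6.35%. Without thinning the shares were 9.43%, 79.6% and 62.4% for Isg15, 24.8%, 43.6% and 28.9% for Cdkn1a, 1.76%, 8.39% and 7.14% for Top2a and 1.56%, 7.36% and 6.77% for Mki67.

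Top2a UMIs were also seen outside the cycling-like cluster, from a source not tested here. In the luminal duct-like cluster a Top2a UMI was seen in 0.476% of control, 0.732% of photon and 1.15% of proton cells after thinning. Median depths there were 3936, 3331 and 3310 UMIs. Shares were higher in cluster 4, at 4.72%, 13.3% and 17.5%, with median depths of 3041, 3222 and 3079 UMIs. In the cycling-like cluster a Top2a UMI was seen in 50.9% of photon and 51.7% of proton cells, at 4684 and 3855 UMIs. That cluster held 430 of the 762 photon cells and 224 of the 580 proton cells with a Top2a UMI. Top2a outside it was therefore not confined to the low shares of the luminal duct-like cluster. The order of photon and proton for Top2a and Mki67 turned with thinning and is not read. No cell class known to lack Isg15 or Cdkn1a was measured.

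**Figure D5:**
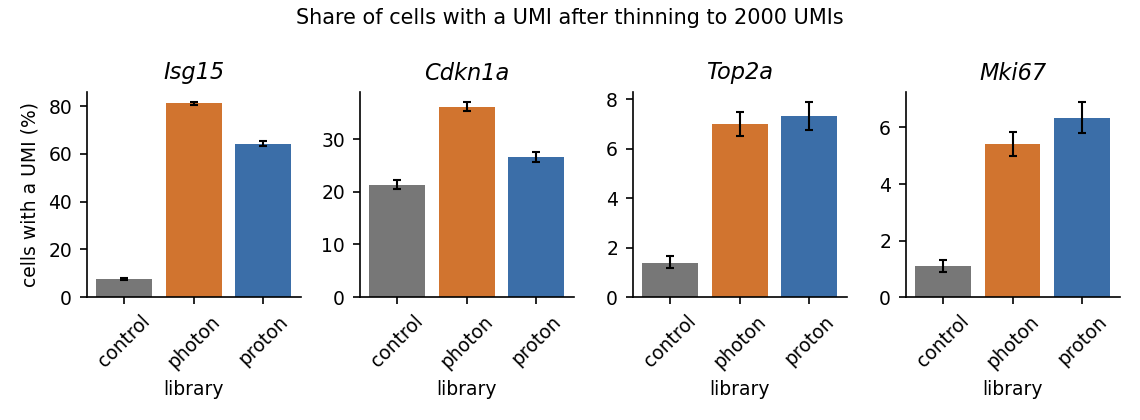
Percent of cells with at least 1 UMI of Isg15, Cdkn1a, Top2a and Mki67 after thinning to 2000 UMIs, 1 bar per library, with exact 95% binomial intervals for counting error. Control is lowest for each gene, at 7.55% for Isg15 and 1.39% for Top2a.

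Set side by side, the irradiated libraries were compared in their difference from control. Of 5846 genes 193 were higher in both, among them Isg15, Ifit3, Ccl5 and B2m, and 114 were lower in both, among them Ifi27, Aox3 and Orm1, while 12 went opposite ways. Across genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.56 and the covariance 0.221. The ratios share 1 control library, and 100 simulated pairs without effects gave a mean r of 0.51 and a mean covariance of 9.03e-04, a difference in covariance of 0.220. Singly, 341 of these genes were higher in photon and 632 in proton, and 466 and 892 were lower. No simulated pair had a gene higher or lower in both (0), but these pairs hold counting noise only. Under such noise the counting rule called 0 unchanged genes, so this value of 0 was bound to come out and nothing is read from it. The single control library cannot be split, so part of the excess and of the shared genes may come from it, and without the interferon, MHC class I and sensing lists r was 0.44 over 5802 genes.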

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

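All tests in this part were chosen after the results they bear on had been seen.

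A signal appeared in barcodes that the main cell filter left out, which only the alternative with a loose filter used. Among barcodes left out by the cell filter (1047 in control, 885 in photon and 569 in proton), Isg15 stood at 258.2 CPM in photon (149 UMIs) and 328.5 CPM in proton (139 UMIs), against 13.8 CPM in control (9 UMIs), ratios of 18.7 (9.59 to 41.7) and 23.8 (12.2 to 53.1).

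Interferon-stimulated genes were higher in both irradiated libraries, with Isg15 at 25.7 and 13.8 times control. A different mixture of cell classes is argued against, because the lower of the list medians with the mixture held equal was still 2.81 on the log2 scale. Free RNA from cluster 9 (155 photon, 62 proton and 1 control cells, led by Ccl5, Cxcl10 and Rsad2) stays open in part. Each member sets an upper limit to the share of the list's UMIs in other cells that a source of that composition could supply. The rule of this test took the fifth lowest limit of 33, which was 28.4% in proton and 26.4% in photon. A source of fixed composition must keep within the limit of every member, so this rule is loose. The lowest limit, of Rsad2 alone, was 6.35% in proton and 6.32% in photon. Even by the looser rule such a source could not supply most of these UMIs. Cluster 9 itself held 2.77% of the list's UMIs in photon and 1.14% in proton. An earlier form of the test, in which 9 of 33 members differed 2-fold in their share of the list, did not decide. Any other difference between cultures or library preparations cannot be told apart from irradiation with 1 library per group. Irradiation itself remains an open, untested explanation.

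The proton library differed from the photon library in many genes, 1318 higher and 948 lower. Gene length may account for most of both: after centring within length classes, 212 (16.1%) of the higher and 413 (43.6%) of the lower genes kept their place, although an earlier form of the test with a looser bound, which counted any 618 lower genes, had pointed the other way for the lower ones. A few genes taking most of the counts is argued against by their share, since the 10 genes of the largest rise held 6.00% of proton and 3.58% of photon UMIs. With them left out 860 lower genes stayed lower, but a share this small could move few genes past the cut, so that count decides nothing. What sets the length trend was not tested, and with 1 library per group a difference in library preparation or nuclear RNA cannot be told apart from the kind of radiation. The kind of radiation stays open and untested.

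Cell cycle genes were lowest in the control library, with Mki67 at 11.0, 37.4 and 44.1 CPM in control, photon and proton. Low-depth cells of cluster 5, mostly control, are argued against as the source, because without them the lower G2 and M phase median was 1.36. Depth per cell is argued against as well: after thinning, the lower limit of the lower irradiated share of cells with a Top2a UMI was 3.95 times the upper limit of the control share. After thinning, fewer control cells held a Top2a UMI, 1.39% against 7.00% in photon and 7.31% in proton. Fewer cycling cells in the control culture may thus account for part of the pattern. With the class mixture held equal the G2 and M phase medians were 0.469 and 0.475. That mixture includes the cycling-like cluster, with 100 control cells and medians of -0.62 and -0.76. Holding its share equal takes out differences in that share by design, so the lower medians do not weigh this explanation. Within clusters 0 to 6 the medians lay between 0.0979 and 2.21 in photon and between 0.456 and 2.51 in proton. In proton the summed genes stood at 0.83 to 0.872 times control in clusters 0, 3 and 5. No direction is read from the cluster shares, and why the cultures differed was not tested. With 1 library per group, growth differences between cultures cannot be told apart from irradiation, which stays open.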

How the results depend on the processing

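The alternatives without cluster 5, without the highest doublet scores, without the leading genes of named clusters and with gene length centring were chosen after seeing the data. No paired analysis was possible because each group is 1 library and cells are not tied to animals. Keeping doublets is the reported analysis itself and is not counted. A count stayed close within 1.5-fold, a list median within its bootstrap interval and a share within its counting interval, and only lists outside the central 95% of matched random lists can reverse. Of 1010 recomputed values for 97 results, 890 stayed close, 116 moved and 4 reversed. The kinds differed: 828 of 864 list medians and 56 of 78 gene counts stayed close, but only 4 of 42 class shares and 2 of 24 shares of cells with a UMI. Staying close does not mean a kept sign: 54 of 864 list medians changed sign, 46 of them within that interval, 4 moved and the 4 reversed, and the interferon median stayed between 2.66 and 3.49 against control under every alternative. No squamous-like cluster was found at Leiden resolution 0.25 or without the leading genes. Except where fewer genes, a higher fold or fewer UMIs per cell set the value, the cause was not tested. Depth limits shares of cells with a UMI, for which no other choice was varied.

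The numbers of genes at least 1.5-fold higher, photon against control, and lower were 519 and 727 at a mean CPM of at least 10, 113 and 139 at 100, 132 and 49 at a fold of 2, and 143 and 80 with the class mixture held equal. The lower genes numbered 267 when scaled by the median of gene ratios and 209 centred within gene length classes. In proton against control there were 1075 higher genes at a CPM of 10, 213 higher and 304 lower at 100, and 202 and 265 at a fold of 2. For genes at least 1.5-fold higher, proton against photon, and lower the numbers were 419 and 364 at a CPM of 100, 181 and 226 at a fold of 2, 420 and 618 centred within length classes, and 519 higher with the mixture equal.

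The S phase median in photon against control was 1.19 with median scaling, 0.291 with the mixture equal and 0.626 for members with a CPM of 25. The G2 and M phase median there was 0.469, 2.40 without the deepest 5% of cells, and 1.27 at a CPM of 25. In proton against control the S phase median was 0.156 and 0.238, and the G2 and M phase median 0.475 and 0.305, with the mixture equal and at a CPM of 25. The correlation of photon and proton log2 ratios across genes was 0.536 at a CPM of 100 and 0.617 with the mixture equal. Among lists outside that central 95%, signs reversed for the median log2 ratio of DNA repair, photon against control (-0.0999 as a mean over cells, -0.0718 with the mixture equal), EGF family ligands in photon (-0.148 for members with a CPM of 1) and G2 and M phase in proton against photon (0.003 with the mixture equal).

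Percent of cells luminal duct-like in control, photon and proton was 3.51, 17.4 and 17.4 under the loose filter, 3.22, 16.4 and 10.1 at Leiden resolution 0.25, 2.8, 16 and 12.1 with response genes kept, 3.56, 16.1 and 13.9 without the highest doublet scores, and 17.2, 26.1 and 14.8 without the leading genes. It was 5.86 in control and 20.4 in proton under the strict filter, 22 in photon and 20 in proton at resolution 1.0, and 17.7 and 17.9 there with genes centred within libraries. Percent of cells squamous-like in control, photon and proton was 8.18, 8.19 and 5.29 under the loose filter, 14.8, 11.3 and 5.34 under the strict one, 11.9, 10.3 and 4.77 at resolution 1.0, 11.9, 7.76 and 7.6 with genes centred, 14.9, 11.3 and 4.99 without the highest doublet scores, and 13.9 in control and 7.18 in photon with response genes kept.

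Percent of cells with a UMI of Isg15 in control, photon and proton was 3.6, 59.9 and 41.6 when thinned to 1000 UMIs and 9.43, 79.6 and 62.4 when not thinned. Cdkn1a gave 11.7, 23.1 and 15 thinned to 1000 and 24.8, 43.6 and 28.9 not thinned. Mki67 gave 0.581, 2.55 and 3.06 thinned to 1000, and 1.56 in control and 7.36 in photon not thinned. Top2a gave 0.755, 3.39 and 3.45 thinned to 1000, and 1.76 in control and 8.39 in photon not thinned.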

Other observations

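The genes in this part were chosen after their values were seen, and nothing here was planned or tested.

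Interferon genes themselves were seen at low counts, and mostly in 1 small cluster. The type III interferon gene Ifnl2 had 1 UMI in control, 36 in photon and 9 in proton, and Ifnl3, its near-identical neighbour on chromosome 7, had 0, 25 and 5, and the split of reads between them is uncertain. The type I interferon gene Ifnb1 had 0, 16 and 16. Ifnl2 stood at 30.3 times control in photon (5.10 to 1230) and 9.69 times in proton (1.34 to 425), each over the 1 control UMI. With the class mixture held equal, which leaves cluster 9 out, the log2 ratios of Ifnl2 were 1.487 and 5.048 against 4.922 and 3.277, so the order of photon and proton is not read. Of the UMIs of these genes, cluster 9 held 33 of Ifnl2, 25 of Ifnl3 and 11 of Ifnb1 in photon, and 6, 3 and 14 in proton. The same cluster held Ccl5 at 3817 CPM in photon and 10980 CPM in proton, and Cxcl10 at 2413 and 1176 CPM. It counted 155 photon and 62 proton cells and 1 control cell.

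Ifi27 and Ifi27l2a, neighbours on chromosome 12 and members of 1 gene family, went opposite ways. Ifi27 stood at 201, 33.5 and 23 CPM in control, photon and proton, and Ifi27l2a at 203, 3810 and 5803 CPM. The opposite directions held in each of clusters 0 to 4, 6 and 7, where Ifi27 stood at 0.0552 to 0.203 times control and Ifi27l2a at 12 to 71.8 times. In cluster 5 Ifi27 rested on 1 UMI in proton.

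Some markers of ductal and squamous cells also differed. Krtdap in the squamous-like cluster stood at 139, 857 and 2394 CPM in control, photon and proton, while it was lower than control in cluster 2 (0.496 times in photon and 0.709 in proton) and cluster 7 (0.634 and 0.544). The scaffold gene Sorbs2 stood at 20.1, 54.5 and 94.8 CPM, and Fxyd2, a regulator of the sodium pump, at 187, 117 and 64.6 CPM over all cells. With the class mixture held equal Sorbs2 stood at 1.78 times control in photon and 2.73 times in proton, against 2.72 and 4.72 times over all cells. Fxyd2 stood at 0.674 times control in photon, 0.669 times in proton and 0.992 times photon in proton at that mixture, and in proton it stood at 0.297 to 0.373 times control within clusters 2, 3, 4 and 6 but at 1.53 times (1.32 to 1.76) within cluster 0. The remaining clusters are not given, so no direction is read for Fxyd2 within clusters.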
